A study of Mus musculus with 8 samples.

How the data were processed

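Total RNA was purified from 30 mg of the left kidney of each of 8 mice, and Cy3-labelled cRNA was made from 50 ng of it with a low-input kit, per the labels' protocols. Each sample was hybridised to 1 array of an 8-array Agilent mouse slide and read in 1 colour. The mice fall into 4 groups of 2 by their titles. The labels number the mice separately, so the 2 samples of a group were treated as separate animals.

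The scanner output was made with Agilent Feature Extraction 12.0.3.1, per the submitters' processing notes and the file headers. Its processed signal is an intensity, background-subtracted and detrended within the array and not scaled between arrays, per the file headers; the raw mean and local background intensity of each spot are given beside it, with flags of 0 or 1 for spot quality, per the file headers. The deposited series table holds a linear ratio per probe. From its values, each probe was divided by its median over the 8 arrays, and the scaling between arrays before that step is not given in the sources used here. The median ratio of the arrays was 1.00 and 0.992 in sham, 0.998 and 0.998 in IRI, 1.00 and 1.02 in mimic and 1.00 and 0.995 in control-miRNA mice. The ratios were used only as an alternative. Both tables name every column by a sample, and 0 value columns were left unused. All 8 arrays lay on 1 slide and had 1 scan time, so neither could act as a batch. Slide rows held sham and IRI arrays in row 1 and mimic and control-miRNA arrays in row 2, so the row cannot be told apart from the injection. Sham and mimic arrays lay in columns 1 and 2, and IRI and control-miRNA arrays in columns 3 and 4, so the slide column as a covariate covers only differences within these column pairs.

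Gene names in the files are those of the array design. Of 56605 distinct probes 33767 were named through their RefSeq accession with a RefSeq gene table of assembly GRCm38, 9866 through a current symbol, 310 through an older symbol, and 12662 kept the name in the file. Probe positions are those of build mm9 in the files. Control spots and spots with a non-uniformity or population outlier flag (79 to 127 per array) were left out, and 0 spots were saturated. The log2 of the processed signal minus the array's 75th percentile was averaged over the spots of a probe. Probes were kept if well above background on both arrays of at least 1 group, which left 32218. The probe with the highest mean over the 8 arrays stood for its gene, and other probes that gave the opposite sign are named in the text.

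The tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 8 arrays with a mean per group, so that the groups share 1 estimate of the spread (6.84 degrees of freedom after moderation). P-values were adjusted by Benjamini-Hochberg over 21264 genes, with a threshold of 0.05. Errors of log2 differences are moderated standard errors. Where a gene was not well above background on any array of a group, the text gives a bound, "at least N-fold". It is the mean of the bright group over the mean of the dim one, in which each dim array takes the higher of its own value and the lowest signal among probes well above background. Gene lists, 38 in all, were fixed before the data were examined, as were the groups, models, other settings (except those named at the end) and the rule for named genes. The lists cover cell types of the kidney, other tissues that a sample could hold, tubular injury, pathways of inflammation, stress, cell death and metabolism, and sex-linked transcripts as a check. They were tested with camera (preset correlation 0.01), camera with an estimated correlation and fry, adjusted over the 38 lists of a comparison. In IRI against sham 0 of 26 camera calls held with an estimated correlation, in mimic against control miRNA 0 of 7, in mimic against IRI 0 of 9 and in control miRNA against IRI 0 of 8.

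The named genes are, per comparison, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (or the 5 smallest p per direction where fewer than 5 pass), leaving out clone, predicted and accession names, up to 4 members of each list by smallest p, and 19 genes fixed in advance. Results for some of these genes are not reported here. The response of injury genes to the mimic was measured on genes called with at least a 2-fold change in IRI against sham. A planned test of genes with a seed match of the mimic in the 3' untranslated region was not run, since no transcript sequences were used here.

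The tests were tried on simulated data with the real genes' means and spreads and 200 changed genes among 21263. For IRI against sham the share recovered was 13.4% at a log2 change of 1, 88.1% at 2 and 98.5% at 3. For mimic against control miRNA it was 19.4%, 92.5% and 93.9%. For mimic against IRI it was 10.4%, 95.5% and 97.0%, and for control miRNA against IRI 13.4%, 94.0% and 98.5%. False calls made up 6.16% to 8.28% of all calls. The simulated noise was independent between genes and held no effect of array brightness.

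Alternatives changed 1 choice at a time: normexp background correction with an offset of 50, quantile normalization, scaling to the median of probes well above background on all arrays, the deposited ratios, no filter or a stricter filter on dim probes, the mean of a gene's probes, only the groups compared, trended and robust variance, array weights, slide column as a covariate, other thresholds, and leaving out each array. Array brightness as a covariate and a fit without both mimic arrays were added after seeing the data. Both mimic arrays were dimmer than all others, so this covariate can hardly part brightness from the mimic. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.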

Results

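Gene expression was measured with 1-colour arrays in the left kidney of 8 mice, taken 24 h after surgery. The 4 groups held 2 mice each, which are named here by their group and the mouse number in the labels. Sham mice (1 and 4) had a midline incision only. IRI mice (30 and 34) had the right kidney removed and the vessels of the left kidney clamped for 45 min and then released, a model of acute kidney injury by ischaemia and reperfusion. Mimic mice (6 and 7) and control-miRNA mice (1 and 5) had the same injury 2 days after a tail vein injection of 5 nmol of a small RNA in 200 µl, bound to polyethylenimine nanoparticles, a cationic polymer that carries nucleic acids into cells. The small RNA was a mimic of miR-5100 in the mimic mice and a control miRNA in the control-miRNA mice. No probe on the array was named for miR-5100, so its level was not measured.

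The number of arrays limits the precision of every value below. The p-values of single genes measure spread between animals, pooled over the 4 groups of 2 mice. Over genes, the SD of the log2 difference between the 2 mice of a group was 0.33 in sham and 0.39 in IRI. It was 0.51 in control-miRNA and 0.67 in mimic mice. The pooled errors may therefore be too small for the mimic comparisons and too large for IRI against sham. Camera p-values with the preset correlation compare a list's genes with all other genes, so they do not measure spread between animals. Between 53.2% and 58.8% of the 59305 non-control spots were well above background on an array. The 75th percentile of the processed signal was 408 and 476 on the sham arrays, 468 and 600 on the IRI arrays, 500 and 416 on the control-miRNA arrays, and 308 and 242 on the mimic arrays. Across 21264 genes the log2 levels of the 2 mice of a group correlated at r = 0.994 in sham, 0.992 in IRI, 0.987 in control-miRNA and 0.975 in mimic mice (across genes, which are not independent replicates). Mimic 6 correlated more closely with IRI 30 (0.983), control-miRNA 5 (0.983) and control-miRNA 1 (0.976) than with mimic 7, and less closely with IRI 34 (0.971). The first principal component carried 48.6% of the variance and parted the sham arrays from the injured ones, of which mimic 7 lay nearest to sham. The second carried 31.3%, and over the 8 arrays it correlated with the log2 of the array's 75th percentile signal at r = 0.983 (exact two-sided permutation p = 2.48e-05, adjusted p = 4.96e-05 over the 2 components) and rho = 1 (exact p = 4.96e-05, adjusted p = 9.92e-05). Without mimic 6 and mimic 7, the 2 arrays farthest from the median brightness, r was 0.992 over the other 6 arrays.

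**Figure D1:**
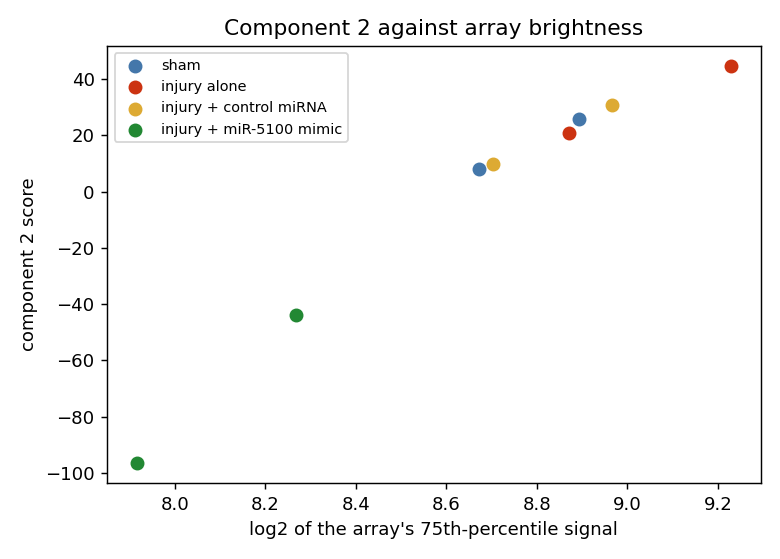
Score on component 2 of the gene levels (vertical axis, no unit) against the log2 of each array's 75th percentile signal (horizontal axis), with 1 point per array and a colour per group. The 8 arrays follow 1 line (r = 0.983), with both mimic arrays at its dim end.

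Injury alone against sham asked what the injury surgery changed in the left kidney at 24 h. IRI mice also lost the right kidney and sham mice did not, so clamping and that removal cannot be told apart. Injury below means both together. Genes of the injured tubule rose most. Of the 30 measured members of the tubular injury list, 28 rose and none fell, with a mean log2 difference of 3.88 (camera adjusted p = 1.03e-24, adjusted p = 0.313 with an estimated correlation). Krt20, a keratin, rose by 10.25 ± 0.40, adjusted p = 0.000291 (log2 difference ± SE, n = 2 mice per group, as in all values below), and Timp1, an inhibitor of matrix metalloproteinases, by 5.33 ± 0.21, adjusted p = 0.000291. Havcr1, which encodes the injury marker KIM-1, was not well above background in sham kidneys and was at least 541-fold higher in IRI kidneys (adjusted p = 0.000261). Lcn2, which encodes the iron-carrier-binding protein NGAL, rose by 7.75 ± 0.51, adjusted p = 0.000909, and Spp1, which encodes osteopontin, by 3.57 ± 0.18, adjusted p = 0.000630.

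The probe for Havcr1 lies on chromosome 11 from 46592056 to 46592115 and the probe for Krt20 on chromosome 11 from 99289776 to 99289835, both in mouse build mm9 as the array files give it. Other genes with the largest rises were the fibrinogen beta chain Fgb (7.20 ± 0.63, adjusted p = 0.00137) and the neutrophil chemokine Cxcl1 (6.25 ± 0.41, adjusted p = 0.000909). Others were below background in sham kidneys, namely Vgf (at least 196-fold, adjusted p = 0.00316), Sprr2f (at least 192-fold, adjusted p = 0.00101), the protease inhibitor Slpi (at least 141-fold, adjusted p = 0.000970), the interleukin 36 family member Il1f6 (at least 81.5-fold, adjusted p = 0.000630) and the matrix metalloproteinase Mmp7 (at least 24.5-fold, adjusted p = 0.00565). The probes of Slpi and Vgf disagreed in size. Another probe of Slpi gave a log2 difference of 0.04, and another of Vgf gave 1.70.

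Transcripts of every nephron segment tested had negative means. Of 46 proximal tubule genes 26 fell and 1 rose (mean -1.54, camera adjusted p = 3.98e-11, adjusted p = 0.313 with an estimated correlation). Among them were the phosphate transporter Slc34a1 (-2.67 ± 0.30, adjusted p = 0.00287), the endocytic receptor megalin, Lrp2 (-1.90 ± 0.20, adjusted p = 0.00215), the cytochrome Cyp2e1 (-2.80 ± 0.24, adjusted p = 0.00124) and the amino acid transporter Slc7a13 (-5.48 ± 0.63, adjusted p = 0.00310). In the thick ascending limb list 7 of 18 genes fell and none rose (mean -1.37, camera adjusted p = 0.000610, adjusted p = 0.447 with an estimated correlation). The sodium transporter Slc12a1 fell there (-3.14 ± 0.59, adjusted p = 0.0155), while Umod, which encodes uromodulin, did not pass the test (-0.09 ± 0.26, adjusted p = 0.840). In the distal convoluted and connecting tubule 7 of 16 fell (mean -1.06, camera adjusted p = 0.00154, adjusted p = 0.447 with an estimated correlation), led by the calcium-binding proteins Pvalb (-3.96 ± 0.41, adjusted p = 0.00219) and Calb1 (-1.54 ± 0.24, adjusted p = 0.00913). In the collecting duct 8 of 23 fell and 1 rose (mean -0.63, camera adjusted p = 0.00529, adjusted p = 0.447 with an estimated correlation). The podocyte list had 5 of 19 genes lower (mean -0.72, camera adjusted p = 0.0199, adjusted p = 0.650 with an estimated correlation). The largest falls among all named genes included Pde6a (-5.31 ± 0.30, adjusted p = 0.000735), Nccrp1 (-5.50 ± 0.69, adjusted p = 0.00414) and Ldc1 (-5.29 ± 0.97, adjusted p = 0.0144). Adgrg4 (at least 31.1-fold lower, adjusted p = 0.00783), Slitrk6 (at least 21.3-fold, adjusted p = 0.0421), the mitochondrial carbonic anhydrase Car5a (at least 20.9-fold, adjusted p = 0.00202) and the potassium channel Kcnt1 (at least 16.8-fold, adjusted p = 0.00144) were below background after injury. The log2 differences of Kcnt1 probes ran from -6.28 to -0.62. Mep1b (-6.17 ± 1.09, adjusted p = 0.0124) and C8a (-5.79 ± 1.52, adjusted p = 0.0425) were above background on 1 of the 2 IRI arrays.

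Of 34 cytokines and NF-kB targets 20 rose and none fell (mean 1.94, camera adjusted p = 1.38e-11, adjusted p = 0.313 with an estimated correlation). Csf1, a growth factor of macrophages, rose by 2.23 ± 0.19, adjusted p = 0.00121. The receptor antagonist gene Il1rn (at least 11.8-fold higher, adjusted p = 0.000909) and Il6 (at least 2.47-fold higher, adjusted p = 0.0202) were below background in sham kidneys, while Tnf (-0.62 ± 0.23, adjusted p = 0.112) and Ccl2 (1.52 ± 0.77, adjusted p = 0.212) did not pass the test. Among immediate early genes, which respond within minutes and many of which encode transcription factors, 21 of 27 rose (mean 2.10, camera adjusted p = 4.23e-14, adjusted p = 0.313 with an estimated correlation). Fos rose by 3.35 ± 0.33, adjusted p = 0.00180 and Myc by 3.39 ± 0.30, adjusted p = 0.00148. NRF2 targets, which code for antioxidant enzymes, had 14 of 28 members higher (mean 1.18, camera adjusted p = 1.84e-07, adjusted p = 0.367 with an estimated correlation), including Hmox1 (3.69 ± 0.34, adjusted p = 0.00159) and Cbr3 (5.54 ± 0.42, adjusted p = 0.000970). Of 24 p53 targets 10 rose and 1 fell (mean 0.91, camera adjusted p = 0.00154, adjusted p = 0.447 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 3.87 ± 0.57, adjusted p = 0.00729 and Trp53 itself by 1.03 ± 0.24, adjusted p = 0.0303. Cell cycle genes had 7 of 38 members higher and none lower (mean 0.94, camera adjusted p = 0.000312, adjusted p = 0.560 with an estimated correlation). The replication helicase subunits Mcm2 (1.96 ± 0.26, adjusted p = 0.00522) and Mcm3 (2.56 ± 0.42, adjusted p = 0.00988) were among them. The heat shock list (mean 0.51, adjusted p = 0.00529) had 6 of 21 members higher, including Hspb1 (3.01 ± 0.31, adjusted p = 0.00216). The unfolded protein response (mean 0.51, adjusted p = 0.0293) had 6 of 28 members higher and 1 lower (adjusted p = 0.114 with fry). The hypoxia list (mean 0.41, adjusted p = 0.0199) had 7 of 29 higher and 2 lower. With an estimated correlation the adjusted p was 0.447, 0.447 and 0.367 for these lists.

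Genes of cell death changed in part. Of 30 pro-apoptotic genes 7 rose and none fell (mean 0.31, camera adjusted p = 0.0277, adjusted p = 0.447 with an estimated correlation). The initiator caspase Casp8 rose by 1.69 ± 0.20, adjusted p = 0.00346 and the pore-forming Bak1 by 1.86 ± 0.22, adjusted p = 0.00350. Casp9 (-0.26 ± 0.16, adjusted p = 0.297), Bax (0.32 ± 0.15, adjusted p = 0.192) and Fas (-0.07 ± 0.17, adjusted p = 0.787) did not pass the test, nor did Bcl2 (-0.30 ± 0.21, adjusted p = 0.359), and another probe of Fas gave the opposite sign. Of 15 anti-apoptotic genes 5 rose (mean 0.53, camera adjusted p = 0.00865, adjusted p = 0.313 with an estimated correlation), with Bcl2l1 at 1.19 ± 0.21, adjusted p = 0.0119. The necroptosis and pyroptosis list had 6 of 15 members higher (mean 0.73, camera adjusted p = 0.00865, adjusted p = 0.443 with an estimated correlation), and the necroptosis effector Mlkl rose by 3.58 ± 0.39, adjusted p = 0.00258. Ferroptosis and iron genes had 7 of 18 higher (mean 1.01, camera adjusted p = 0.00764, adjusted p = 0.424 with an estimated correlation).

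Markers of immune and stromal cells went different ways. Of 17 neutrophil genes 9 rose (mean 1.70, camera adjusted p = 0.000714, adjusted p = 0.447 with an estimated correlation). The calcium-binding S100a8 rose by 3.55 ± 0.36, adjusted p = 0.00218 and S100a9 by 2.96 ± 0.39, adjusted p = 0.00503. Lcn2 is in this list and is also made by injured tubule. The macrophage list had 4 genes higher and 4 lower (mean 0.18, median -0.27, adjusted p = 0.629), with Cd14 at 4.21 ± 0.25, adjusted p = 0.000735 and the growth factor receptor Csf1r at -1.70 ± 0.20, adjusted p = 0.00367. T and NK cell genes were lower (6 of 20 fell, mean -1.31, camera adjusted p = 0.000718, adjusted p = 0.447 with an estimated correlation), as were B cell genes (2 of 8 fell, mean -0.95, camera adjusted p = 0.0205, adjusted p = 0.447 with an estimated correlation). Of 21 endothelial genes 3 fell (mean -0.52, camera adjusted p = 0.00865, adjusted p = 0.447 with an estimated correlation), including the transcription factor Erg (-1.43 ± 0.24, adjusted p = 0.0112). The fibroblast and matrix list showed no shift of its mean (0.13, adjusted p = 0.529), with the matrix protein gene Tnc at least 5.48-fold higher (adjusted p = 0.00233) and Dcn lower (-2.45 ± 0.31, adjusted p = 0.00416). Another probe of Tnc gave a log2 difference of 1.57.

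Of 40 genes of respiration and the TCA cycle 4 fell (mean -0.44, camera adjusted p = 3.20e-05, adjusted p = 0.313 with an estimated correlation), including Idh2 (-1.08 ± 0.16, adjusted p = 0.00687). Fatty acid oxidation genes had a mean of -0.00206 (adjusted p = 0.709), since Pdk4 (4.09 ± 0.52, adjusted p = 0.00429) and Fabp1 (2.73 ± 0.23, adjusted p = 0.00123) rose while Hao2 (-3.04 ± 0.33, adjusted p = 0.00260) and Acadm (-1.49 ± 0.26, adjusted p = 0.0116) fell. The remaining lists had these means and camera adjusted p: interferon response 0.18 and 0.0171 (adjusted p = 0.560 with an estimated correlation; mean -0.05 without IRI 34 and 0.42 without IRI 30), complement and acute phase 1.37 and 0.165, lysosome -0.10 and 0.577, cholesterol synthesis -0.24 and 0.343, circadian clock -0.55 and 0.0932. Lists of other tissues gave erythroid -1.73 and 0.0175 (adjusted p = 0.447 with an estimated correlation), hepatocyte -1.34 and 0.0171 (adjusted p = 0.447 with an estimated correlation), adrenal cortex -0.74 and 0.585, adipose tissue 0.55 and 0.731, urothelium 0.58 and 0.275, and skeletal muscle -0.47 and 0.674. The sex-linked transcripts, kept as a check of the samples, had a mean of -0.41 (0.269).

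Over all genes limma called 3887 of 21264 in this comparison, 2013 higher and 1874 lower, of which 2612 changed at least 2-fold. Of the 26 lists called by camera 0 held with an estimated correlation and 17 held with fry. Calls were lost without IRI 34 for interferon (adjusted p = 0.505), pro-apoptotic (mean 0.23, adjusted p = 0.143), unfolded protein response (0.143), heat shock (0.0713), B cell (0.0606) and hypoxia genes (0.0571), and without a sham array for interferon, pro-apoptotic and B cell genes. With array brightness as a covariate they were lost for pro-apoptotic (mean 0.19, adjusted p = 0.290), B cell (-0.59, 0.120), hepatocyte (-0.91, 0.0626), hypoxia (0.33, 0.0614) and interferon genes (0.16, 0.0504). The count was 799 without sham 1, 863 without sham 4, 860 without IRI 30 and 1076 without IRI 34, and 663 genes stayed called in all of these fits. The count was 1851 with array brightness as a covariate.

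**Figure D2:**
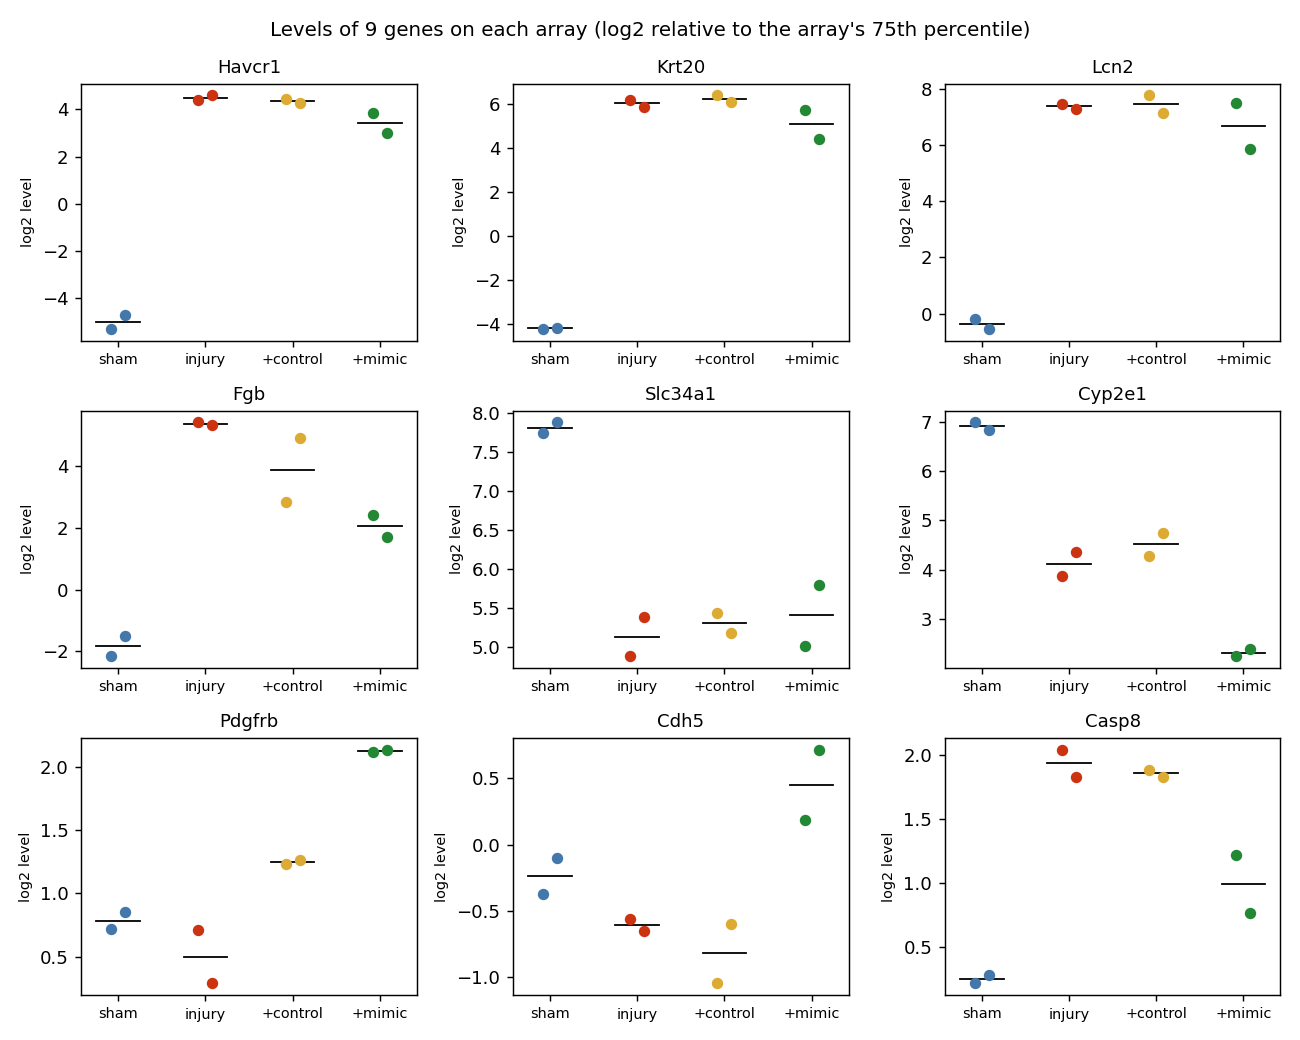
Log2 level of 9 genes (vertical axes, relative to the array's 75th percentile) on each of the 8 arrays, with a bar at the mean of the 2 arrays of a group. Havcr1, Krt20 and Lcn2 lie far higher on every injured array than on both sham arrays.

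The mimic against the control miRNA compared groups that both had the nanoparticles and the injury, and that also differed in place on the slide and in array brightness. Endothelial transcripts lay higher in mimic kidneys, 20 of 21 with a positive log2 difference and a mean of 0.75 (camera adjusted p = 5.86e-05, adjusted p = 0.749 with an estimated correlation and 0.0735 with fry). Fatty acid oxidation genes lay lower, with a mean of -0.63 (camera adjusted p = 0.000125, adjusted p = 0.749 with an estimated correlation), which was -0.35 without mimic 7 and -0.92 without mimic 6. No single gene passed the threshold over all genes. The values below are therefore given as differences and not as changes.

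In the endothelial list 11 genes were higher when adjusted over the list alone, and 0 over all genes. The log2 difference was 1.27 ± 0.25 for the junction protein gene Cdh5, 0.96 ± 0.19 for Emcn and 0.78 ± 0.17 for Eng, each with adjusted p = 0.0670. In the fibroblast and matrix list (mean 0.50, camera adjusted p = 0.0202, adjusted p = 0.749 with an estimated correlation) 4 genes were higher adjusted over the list alone, and the growth factor receptor gene Pdgfrb differed by 0.88 ± 0.19, adjusted p = 0.0670. The mean was 0.27 without control-miRNA 5 (adjusted p = 0.254) and 0.39 without mimic 6 (adjusted p = 0.162). On the mimic arrays the non-coding or unnamed transcripts were also higher than on the control-miRNA arrays, by a median of 0.30 over 6389 genes, while the median of 14875 protein-coding genes was -0.01. The podocyte and B cell lists each had a mean of 0.61 without a camera call. Lists of other tissues, none of them called, had means of 0.53 (adrenal cortex), 0.50 (skeletal muscle), 0.15 (urothelium), 0.11 (adipose tissue), 0.02 (hepatocyte) and -0.71 (erythroid). A mean as large as that of the fibroblast list was therefore not particular to it.

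Of 35 fatty acid oxidation genes 14 were lower adjusted over the list alone, among them the transcription factor gene Ppara (-1.05 ± 0.25, adjusted p = 0.0676) and Acot12 (-1.15 ± 0.31, adjusted p = 0.0709). Probes disagreed for 2 other members. Crot differed by -0.89, with another probe at 0.83. Hadhb differed by -0.85, while 2 of its 3 probes had the opposite sign, up to 0.68. The same non-coding shift and dim signal went with this list. The proximal tubule list (mean -0.33, camera adjusted p = 0.0248) had 5 genes lower adjusted over the list alone, with Cyp2e1 at -2.20 ± 0.24, adjusted p = 0.0670 and the organic anion carrier gene Slco1a1 at -2.45 ± 0.39, adjusted p = 0.0670, while Slc34a1 differed by 0.10 ± 0.30, adjusted p = 0.833 and Lrp2 by -0.19 ± 0.20, adjusted p = 0.521, both with other probes of opposite sign. The call of this list was lost without control-miRNA 5, where its mean was -0.13. Without control-miRNA 1 the mean moved the other way, since the list lay at 3.52 on control-miRNA 1 and 3.92 on control-miRNA 5. Camera also called lower means for respiration (-0.32, adjusted p = 0.00574), pro-apoptotic genes (-0.31, adjusted p = 0.0258) and the hypoxia list (-0.28, adjusted p = 0.0287). All 4 had adjusted p = 0.749 with an estimated correlation. With array brightness as a covariate the pro-apoptotic mean turned to 0.03 (adjusted p = 0.690) and the hypoxia mean was -0.06 (adjusted p = 0.502). The pro-apoptotic call was also lost without mimic 7 (adjusted p = 0.0521) and without control-miRNA 1 (0.0533), and those of respiration (0.0628) and proximal tubule (0.228) without mimic 6.

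Among pro-apoptotic genes 3 were lower and 1 was higher adjusted over the list alone. Casp8 differed by -0.86 ± 0.20, adjusted p = 0.0670 and the executioner caspase Casp6 by -0.96 ± 0.20, adjusted p = 0.0670. The probe for Casp8 lies on chromosome 1 from 58901601 to 58901660 (mm9). Bax (0.28 ± 0.15, adjusted p = 0.226), Casp9 (-0.30 ± 0.16, adjusted p = 0.235), Bcl2 (-0.17 ± 0.21, adjusted p = 0.596), Bcl2l1 (-0.36 ± 0.21, adjusted p = 0.254) and Fas (0.02 ± 0.17, adjusted p = 0.946) each had a probe of opposite sign. Trp53 differed by 1.22 ± 0.24, adjusted p = 0.0670 and Tnf by 0.56 ± 0.23, adjusted p = 0.145. Of the injury markers, Havcr1 differed by -0.95 ± 0.32, adjusted p = 0.0992, Krt20 by -1.17 ± 0.40, adjusted p = 0.102, Lcn2 by -0.78 ± 0.51, adjusted p = 0.307 and Spp1 by 0.10 ± 0.18, adjusted p = 0.720.

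The genes that injury raised at least 2-fold (1259 genes) were lower in mimic than in control-miRNA kidneys by a mean log2 difference of -0.29 (camera p = 1.95e-07 with the preset correlation and 0.250 with an estimated one). Of them 68.0% had a negative difference, the direction toward sham. The 1353 genes that injury lowered had a mean of 0.25 (camera p = 0.101 with the preset correlation and 0.715 with an estimated one). Of them 63.3% had a positive difference, the direction toward sham. Among all genes tested, 49.7% of the protein-coding and 66.7% of the non-coding or unnamed ones had a positive difference. The lists came from sham and IRI arrays and the means from mimic and control-miRNA arrays, while the estimate of spread behind both is shared by all arrays. With fry the p was 0.136 for the raised and 0.341 for the lowered genes. The mean log2 level of the 1259 raised genes was 0.91 on mimic 6 and 0.52 on mimic 7. It was 1.08 on control-miRNA 1 and 0.93 on control-miRNA 5. For the 1353 lowered genes it was -1.03, -0.58, -1.17 and -0.93 in the same order. The settings that follow chose the injury genes anew in each fit, so their lists can differ from these. The mean of the raised genes was -0.10 without mimic 7 and -0.55 without mimic 6, and that of the lowered genes 0.01 and 0.56. With array brightness as a covariate the means were 0.02 and -0.03. No error between arrays was computed for these means, so they do not settle the part of brightness.

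**Figure D3:**
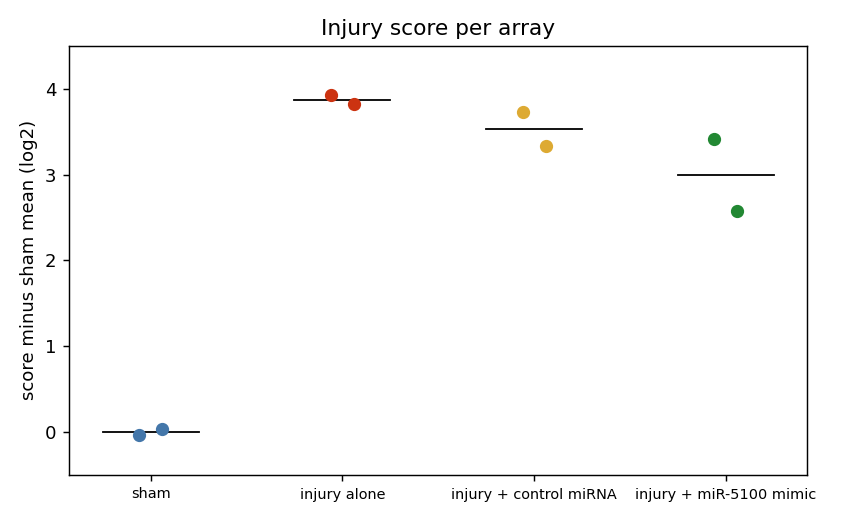
Injury score of each array, the mean of the 1259 raised genes minus the mean of the 1353 lowered genes, relative to the sham mean (vertical axis, log2), with a bar at each group's mean. Mimic 7, at 2.58, lies lowest of the 6 injured arrays, and mimic 6, at 3.42, lies between control-miRNA 5 (3.33) and control-miRNA 1 (3.73).

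Limma called 0 of 21264 genes here, the lowest adjusted p was 0.0670, and 7180 genes had an unadjusted p under 0.05, against 1063 from chance. The count became 5838 with normexp background correction, 1937 with a trended and robust variance, 1486 with only probes well above background on all arrays, and 6318 without mimic 6. It was 0 with array brightness as a covariate, with 726 genes at an unadjusted p under 0.05.

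**Figure D4:**
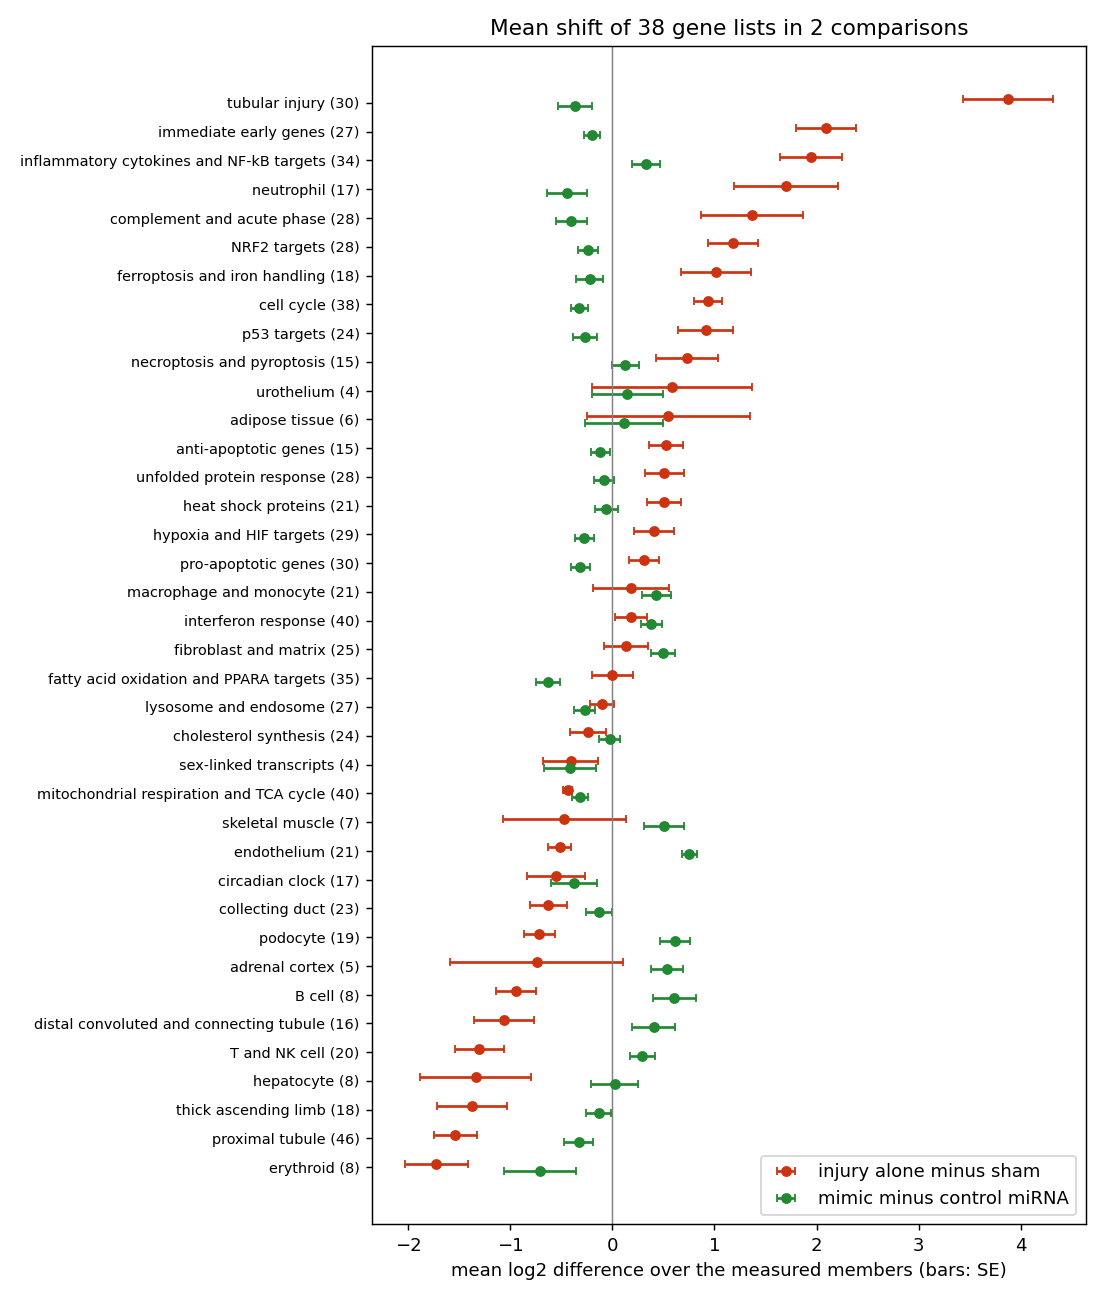
Mean log2 difference of each of the 38 gene lists (horizontal axis; measured members in brackets) for injury alone minus sham and for mimic minus control miRNA, with bars for the standard error over members. The tubular injury list has the highest mean after injury (3.88), and endothelium the highest between mimic and control miRNA (0.75).

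Mimic against injury alone compared the small RNA together with its carrier with no injection. Fibroblast and matrix genes were higher in mimic kidneys, 15 of 25 and none lower, with a mean of 1.19 (camera adjusted p = 1.56e-07, adjusted p = 0.743 with an estimated correlation and 0.0238 with fry). The collagen genes Col6a1 (1.83 ± 0.19, adjusted p = 0.0389), Col5a1 (1.75 ± 0.20, adjusted p = 0.0389) and Col1a2 (1.96 ± 0.24, adjusted p = 0.0389) rose, as did Pdgfrb (1.63 ± 0.19, adjusted p = 0.0389). The probe for Col6a1 lies on chromosome 10 from 76171538 to 76171597 (mm9). The 3 fibrinogen chain genes had the largest falls, with Fgb at -3.32 ± 0.63, adjusted p = 0.0389, Fga at -3.16 ± 0.62, adjusted p = 0.0389 and Fgg at -3.14 ± 0.58, adjusted p = 0.0389.

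Of 21 endothelial genes 9 rose (mean 0.81, camera adjusted p = 4.88e-05, adjusted p = 0.797 with an estimated correlation), among them Eng (0.92 ± 0.17, adjusted p = 0.0389) and the receptor gene Flt1 (1.17 ± 0.23, adjusted p = 0.0389). Macrophage genes had 5 of 21 higher and 1 lower (mean 0.69, camera adjusted p = 0.00664, adjusted p = 0.797 with an estimated correlation and 0.0878 without mimic 6), with the integrin gene Itgam at 2.52 ± 0.48, adjusted p = 0.0389 and the complement gene C1qc at 0.94 ± 0.21, adjusted p = 0.0395. Non-coding or unnamed transcripts were higher by a median of 0.36 in this comparison too, and 1011 of the 2095 genes called higher belonged to that class.

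Lower means were called by camera for fatty acid oxidation (5 of 35 fell, mean -0.68, adjusted p = 4.03e-05), respiration (6 of 40 fell, mean -0.42, adjusted p = 9.35e-05) and proximal tubule (10 of 46 fell, mean -0.37, adjusted p = 0.00646). With an estimated correlation the adjusted p was 0.797, 0.743 and 0.797, and fry held respiration at 0.0238. The fatty acid oxidation mean was -0.39 without mimic 7 and -0.97 without mimic 6, and the proximal tubule call was lost without mimic 6 (mean -0.27). The proximal tubule difference also leaned on IRI 34, where the list lay at 3.92 against 3.61 on IRI 30. The fatty acid carrier Fabp1 (-1.22 ± 0.23, adjusted p = 0.0389), Idh3b of the TCA cycle (-1.59 ± 0.31, adjusted p = 0.0389) and the phosphate transporter Slc17a1 (-2.43 ± 0.40, adjusted p = 0.0389) fell. Hadhb (-0.90 ± 0.21, adjusted p = 0.0429), Crot (-0.97 ± 0.19, adjusted p = 0.0389) and Sdha (-0.94 ± 0.23, adjusted p = 0.0447) passed the test with a probe of opposite sign. Camera also called hypoxia genes (mean -0.28, adjusted p = 0.0276, 0.743 with an estimated correlation), NRF2 targets (mean -0.28, adjusted p = 0.0358, 0.797 with an estimated correlation) and pro-apoptotic genes (mean -0.26, adjusted p = 0.0445, 0.797 with an estimated correlation). With array brightness as a covariate these calls were lost, with means of -0.0016 (adjusted p = 0.888), 0.07 (adjusted p = 0.732) and 0.19 (adjusted p = 0.242). The NRF2 (mean -0.08, adjusted p = 0.217) and pro-apoptotic calls (mean -0.17, adjusted p = 0.128) were also lost without mimic 7. In the last list 4 genes fell, including Casp8 (-0.94 ± 0.20, adjusted p = 0.0391), Casp6 (-1.08 ± 0.20, adjusted p = 0.0389) and the TNF receptor gene Tnfrsf1a (-0.95 ± 0.18, adjusted p = 0.0389).

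Other large rises included the calcium channel gene Trpc6 (2.89 ± 0.58, adjusted p = 0.0389; -0.25 with array brightness as a covariate), Pign (3.04 ± 0.59, adjusted p = 0.0389; -0.16 with that covariate), Marchf1 (2.74 ± 0.49, adjusted p = 0.0389), Nccrp1 (2.88 ± 0.69, adjusted p = 0.0430) and the U1 small nuclear RNA genes Rnu1b1 (2.81 ± 0.41, adjusted p = 0.0389) and Rnu1b6 (2.71 ± 0.40, adjusted p = 0.0389). Tmem207 (at least 3.99-fold higher, adjusted p = 0.0392), Myt1l (at least 3.75-fold, adjusted p = 0.0392) and the microfibril gene Mfap5 (at least 3.49-fold, adjusted p = 0.0389) were below background in IRI kidneys. Large falls included Il1f6 (-2.82 ± 0.44, adjusted p = 0.0389) and Pcdh8 (-2.60 ± 0.33, adjusted p = 0.0389), and the hormone gene Fgf21 was below background in mimic kidneys (at least 3.09-fold lower, adjusted p = 0.0463). Havcr1 (-1.08 ± 0.32, adjusted p = 0.0602), Krt20 (-0.95 ± 0.40, adjusted p = 0.128), Lcn2 (-0.70 ± 0.51, adjusted p = 0.333) and Spp1 (0.10 ± 0.18, adjusted p = 0.718) did not pass the test.

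Limma called 3284 genes, 2095 higher and 1189 lower (63.8% higher; 51.2% after quantile normalization), all with adjusted p of at least 0.0389. The count was 0 without IRI 30, IRI 34 or mimic 7, with only these groups in the fit, with array weights, with the slide column or array brightness as a covariate, and 7514 without mimic 6.

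The control miRNA against injury alone asked what the carrier with a control small RNA did. No single gene passed the threshold. Camera with the preset correlation called 8 of the 38 lists, of which 0 held with fry. Fibroblast and matrix genes had 23 of 25 positive differences (mean 0.70, camera adjusted p = 6.67e-17, adjusted p = 0.658 with an estimated correlation), and 12 were higher adjusted over the list alone. All 38 cell cycle genes had positive differences (mean 0.56, camera adjusted p = 7.58e-05, adjusted p = 0.920 with an estimated correlation). This mean turned to -0.23 without control-miRNA 1 and was 1.35 without control-miRNA 5. Inflammatory genes had 27 of 34 negative differences (mean -0.45, camera adjusted p = 6.00e-07, adjusted p = 0.920 with an estimated correlation), with a mean of -0.23 without IRI 34.

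The log2 difference was 1.30 ± 0.19, adjusted p = 0.417 for Col6a1, 1.49 ± 0.23, adjusted p = 0.443 for the matrix gene Postn and -1.26 ± 0.37, adjusted p = 0.891 for the interleukin receptor antagonist gene Il1rn. Camera also called neutrophil (0.57, adjusted p = 0.000121), thick ascending limb (0.45, adjusted p = 0.000731) and macrophage genes (0.26, adjusted p = 0.0119) higher, and respiration (-0.10, adjusted p = 0.0188) and heat shock genes (-0.13, adjusted p = 0.0312) lower, each with adjusted p = 0.920 with an estimated correlation. Of these only the neutrophil list stayed called without each array in turn, and the thick ascending limb mean was 0.21 without IRI 30 and 0.23 without control-miRNA 5. The heat shock mean turned to 0.02 without IRI 34, and with array brightness as a covariate the heat shock (-0.06, adjusted p = 0.569) and respiration (-0.08, adjusted p = 0.113) calls were lost. The smallest p belonged to Adamtsl2, a regulator of matrix fibrils, at 2.05 ± 0.15, adjusted p = 0.0649, and the matrix gene Smoc2 differed by 2.01 ± 0.24, adjusted p = 0.216. Havcr1 differed by -0.13 ± 0.32, adjusted p = 0.999, Spp1 by -0.00356 ± 0.18, adjusted p = 0.999, and Lcn2 by 0.08 ± 0.51, adjusted p = 0.999 with another probe of opposite sign. Limma called 0 genes at an adjusted p under 0.05, 864 had an unadjusted p under 0.05, and chance gives 1063; the count was 1 with array weights and 1 with only probes well above background on all arrays.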

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

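Brightness as a covariate and the fit without both mimic arrays were chosen after seeing the data; all other alternatives were planned. With 2 arrays per group, leaving out an array leaves a lone array that is assumed to vary like the other groups. No paired analysis was possible because the groups compared share no mouse number. Dim probes limit what the mimic arrays can show, since the lowest log2 signal well above background was -4.21 and -3.90 there and -4.48 to -5.17 on the others. Values that passed the test neither in the fit reported nor in the alternative are not counted as reversed. The test of seed sites was not run. The cause of the changes below was not tested. The brightness covariate cannot settle it, since both mimic arrays were dimmer than all others. In mimic minus control-miRNA it raised the error between arrays from 0.175 to 0.389 for the endothelial mean. For fatty acid oxidation that error rose from 0.246 to 0.547.

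The count of genes called in IRI minus sham was 3887. It was 2436 without a filter on dim probes, 7894 with array weights, 2189 with slide column as a covariate, 6777 with only the groups compared, 1851 with brightness as a covariate, 5939 without both mimic arrays, and 799 to 1076 when an array was left out. Of the 3887 genes 1390 stayed called in all 10 settings planned in advance that kept every array and the threshold. In mimic minus control-miRNA the count of 0 became 5838 with normexp, 1486 with only probes detected on all arrays, 1937 with trended and robust variance and 4763 at an adjusted p under 0.1, and was 0 to 6318 when an array was left out. In mimic minus IRI the count of 3284 became 10315 with normexp, 2188 with quantile normalization, 11850 without a filter on dim probes, 2147 at 2-fold or more and 7275 at an adjusted p under 0.1. It was 0 with array weights, slide column, only the groups compared or brightness as a covariate, and 0 to 7514 when an array was left out. In control-miRNA minus IRI the count of 0 became 1 with only probes detected on all arrays, 1 with array weights and 1 at an adjusted p under 0.1, and was 0 to 0 when an array was left out.

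The mean of the IRI-raised genes in mimic minus control-miRNA, -0.29, kept its sign and its side of the threshold in 20 of 23 alternatives (-0.55 to -0.10 when an array was left out). It was -0.29 with p = 0.250 with an estimated correlation and p = 0.136 with fry, and 0.0175 with brightness as a covariate. Settings that refit the genes also chose the IRI-raised and IRI-lowered genes anew. The mean of the IRI-lowered genes, 0.25, passed the threshold at 0.30 with array weights, 0.30 with only the groups compared, 0.56 without mimic 6 and 0.39 without control-miRNA 5, and ran from 0.00729 to 0.56 when an array was left out.

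Quantile normalization ended 4 of 7 list calls in mimic minus control-miRNA (proximal tubule, pro-apoptotic, hypoxia and respiration) and 5 of 9 in mimic minus IRI (the same and NRF2), and the authors' values ended 3 in each. The count of lists called in mimic minus control-miRNA was 3 with quantile normalization and 22 without a filter on dim probes. Among lists, pro-apoptotic genes turned to 0.0338 in mimic minus control-miRNA and 0.19 in mimic minus IRI with brightness as a covariate, and NRF2 targets in mimic minus IRI to 0.0745. Interferon response in IRI minus sham turned to -0.0549 without IRI 34. In control-miRNA minus IRI, when an array was left out, cell cycle ran from -0.23 (without control-miRNA 1) to 1.35 and heat shock proteins from -0.27 to 0.0231 (without IRI 34). Among the genes named, values turned only in mimic minus IRI. With normexp these were Zxda 0.0695, Cidea 0.45, Serpina3n 0.18 and Apaf1 0.63. Ttc26 was 0.52 with only probes detected on all arrays. With the mean of a gene's probes Crot was 0.0203, Hadhb 0.00478 and Kdm5d 0.61. With brightness as a covariate Pign was -0.16, Trpc6 -0.25, Fem1al 0.31, St6gal1 0.0455, Csf3r -0.15, Hspd1 0.0190, Dnajb9 0.0768, Egln3 0.11, Suclg1 0.24, Nfe2l2 0.32 and Atp6ap1 0.00227. The median over all genes was 0.07 in mimic minus control-miRNA and 0.09 in mimic minus IRI. It was 0.18 and 0.22 with normexp, 0.34 and 0.49 without a filter on dim probes, and -0.03 and -0.04 with brightness as a covariate. Without the filter it was -0.26 in IRI minus sham and 0.12 in control-miRNA minus IRI.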

Other observations

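A few clock genes passed the test in mimic minus IRI, though the circadian list was called in no comparison (camera adjusted p = 0.385 there). Of the 3284 calls in mimic minus IRI, 0 held in all 10 planned settings that kept every array and the threshold. The core activator Arntl rose by 2.48 ± 0.65, adjusted p = 0.0479, and its output gene Dbp fell (-2.51 ± 0.65, adjusted p = 0.0480), with Cry1 at 1.45 ± 0.33, adjusted p = 0.0404 (another probe of Cry1 had the opposite sign). In mimic minus control-miRNA Arntl differed by 2.79 ± 0.65, adjusted p = 0.0670, and its 3 probes ran from 0.64 to 2.79. Interferon-induced genes had a mean of 0.38 in mimic minus control-miRNA (camera adjusted p = 0.0708), with Isg15 at 1.41 ± 0.25, adjusted p = 0.0670 and Usp18 at 1.12 ± 0.20, adjusted p = 0.0670, and the chemokine gene Ccl12 at 2.73 ± 0.48, adjusted p = 0.0670. Within the control-miRNA group the podocyte list was lower on the dimmer array (mouse 5) than on the brighter by a mean log2 difference of -1.47.

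Of the tests below, only that of signal loss along the transcript was written down before its result was seen; the others, and the brightness covariate, were chosen after, and the bound for the tubular share was moved from errors over genes to errors between arrays after its values were seen. The first pattern is the mimic arrays standing apart from the other injured arrays on component 2. By correlation mimic 6 did not stand apart with mimic 7 (r = 0.975), since it lay at 0.983 with IRI 30 and with control-miRNA 5. A lower share of tubular cells would raise all other cell types alike, and stays open. Endothelium exceeded neutrophil markers by 1.20 against control-miRNA but by 0.68 against IRI arrays (SE between arrays 0.49). The 1.20 was 0.52 without mimic 7 and 1.89 without mimic 6. Fibroblast exceeded neutrophil markers by 0.94 and 1.07 (SE 0.31), picked out of 10 gaps as the largest for its error over both comparisons. Loss of signal toward the 5' end would raise probes nearer the 3' end and is argued against, since rho over 4798 probe pairs was -0.304 (across probes, with a trend of opposite sign left unexplained). Lower sample signal may account for the non-coding and unnamed transcripts, whose median was higher on the dimmer array in all 4 pairs of mice of a group (mean 0.11), while for endothelial markers (0.0448), fatty acid oxidation genes (-0.0713) and the probe position trend (mean rho -0.144) the 4 pairs went both ways, and the test leaves this open. These tests first used the sham, IRI and control-miRNA pairs, and the mimic pair was added after those values had been seen: without it the endothelial values were all negative (-0.12, -0.15 and -0.01, mean -0.09; mimic pair 0.46) and fatty acid oxidation had a mean of 0.10, both opposite to what lower signal needs, while rho was negative in all (-0.374, -0.203 and -0.177; mimic pair 0.180), as it needs. With brightness as a covariate the endothelial mean stayed called by camera at 0.60 (adjusted p = 4.22e-06) and fatty acid oxidation at -0.41 (adjusted p = 0.00362), but between arrays their errors were 0.39 and 0.55 (SE, 3 degrees of freedom), so this does not exclude lower signal.

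The second pattern is that genes of the injury response lay nearer sham in mimic than in control-miRNA kidneys. The injury score, relative to sham, was 3.42 and 2.58 in the mimic mice, with a mean of 3.53 ± 0.28 (SD, n = 2) in control-miRNA and 3.87 ± 0.07 in IRI mice, where choosing genes by the IRI and sham arrays favours a high mean and a small spread. The score differed by 0.53 between the injected groups, and 2 of the 3 splits of the 4 injected mice gave a difference as large (highest other split 0.62), too few splits for a share under 0.05. The dimmer array had the lower score in the sham, control-miRNA and mimic pairs and the higher one in the IRI pair, though that choice also narrows the sham and IRI pairs (mean -0.30; -0.12 without the mimic pair, which was added after those values had been seen). Spread between animals, sample signal and an effect of the mimic all remain open.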
